A study of Temnothorax rugatulus with 32 samples.

How the data were processed

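RNA was measured in the brain and the fat body of 16 field-collected queens of the ant Temnothorax rugatulus, 8 old and 8 young, giving 32 libraries in 4 groups of 8. Per the labels' protocols, each queen was decapitated, both tissues were dissected on ice and stored in TRIzol, RNA was extracted with a column kit, and the libraries were built by a sequencing company. The reads of young brain Y-134 were joined from 2 lanes, per the labels. Each library comes from a separate queen within its tissue, so the spread between libraries is a spread between animals.

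The authors deposited 1 table of whole-number read counts for 228763 contigs of a de novo transcript assembly, per the file headers, with no scaling applied. The submitters' processing notes name FastQC 0.11.5, Trimmomatic 0.36, Bowtie, Bowtie2, RSEM 1.3.0 and DESeq2 1.2.10 without saying which step each served. RSEM shares reads between similar transcripts, so the deposited counts may be rounded estimates, and counts of contigs from the same assembly component can be split between them. The assembler is not given in the sources used here. Of the contigs, 3263 had no count in any library. No reference genome was used. Total counts ranged from 13861667 to 33461227 per library, and all 32 count columns were matched to a sample by name.

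The authors also deposited 4 tables of their own comparisons, holding their mean normalised signal per contig, log2 fold change and its error, test score, and p-value with its adjustment, per the file headers. These tables list contigs with an adjusted p-value under 0.05: 169 for age in the brain, 1597 for age in the fat body, 42837 for tissue in young queens and 38180 for tissue in old queens. The mean signal followed from the deposited counts with median-of-ratios scaling to within 1% for 100% of contigs in each table. A positive log2 value in the deposited age tables means higher in young queens. In the deposited tissue tables a positive log2 value goes with higher counts in the brain, whichever way the other sheets name it, and the direction here was taken from the counts.

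Only the 2 deposited age tables describe contigs, by the protein and species of the best database hit. They describe 1073 contigs, of which 848 have a protein name. The plan took descriptions from the count table or the tissue tables, which carry none, so the descriptions of the age tables were used. Those contigs were chosen by the authors on age in these same libraries. A list's direction with age is therefore not independent evidence, and pathways whose contigs the authors did not select are not represented.

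The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts with TMM scaling, keeping contigs that passed filterByExpr (minimum count 10, minimum total count 15), with Benjamini-Hochberg adjustment and a threshold of 0.05. Each comparison was fitted on its own libraries: old minus young in each tissue, fat body minus brain in each age, and, over all 32 libraries, the difference of the age differences between tissues. Values are given as CPM, scaled as in the comparison they belong to, with the SD over 8 libraries. CPM of the age comparisons were scaled within a tissue and are not compared across tissues. Standard errors follow from the fitted log2 difference and its F statistic.

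The 18 gene lists and 10 marker lists were fixed before the data were examined as word patterns on the descriptions. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and with an estimated correlation, against the other described contigs tested. Fry, which asks only whether the contigs of a list move, was run as well. The rule for named contigs was fixed at the same time. For age it takes the 10 named contigs with the smallest adjusted p in each direction that reach 1 CPM in a group, for tissue and for the difference between tissues 8, and for each list up to 4 members, always with 1 contig per description. Contigs without a name were limited to 2 per direction. Vitellogenin, superoxide dismutase and catalase contigs were to be reported whatever their test.

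Brain and fat body with the same number come from the same queen, per the labels. Deviations from the group means correlated between the 2 tissues of a queen at r = 0.329 to 0.401 across contigs, against at most -0.001 for tissues of different queens, and each of the 16 brains matched its own fat body best. The main fits carry no queen term, and fits with the queen as a block were run as alternatives.

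On simulated data with 100 contigs changed 2-fold and 100 changed 4-fold among 27664 contigs, the edgeR test of age in the fat body recovered 5% and 30% of them, with 1 false call among 36. For age in the brain, with 40572 contigs, it recovered 10% and 51%, with 2 false calls among 63. DESeq2 1.42.0 on the same simulated data recovered 15% and 53% for the fat body with 71 false calls among 139, and 28% and 70% for the brain with 83 false calls among 181. For the difference between tissues, 3% and 9% were recovered among 48253 contigs. The tissue comparison recovered 8% and 35% among 35113 contigs in young queens and 7% and 44% among 34574 in old queens. All simulations left the other contigs unchanged and drew libraries independently, without pairing the tissues of a queen. In the real tissue comparisons 57% of contigs in young and 55.8% in old queens were called, so the simulated recovery does not describe them.

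Alternatives covered median-of-ratios scaling, no count filter, at least 1 CPM in 8 libraries, DESeq2, limma-voom with quality weights, counts summed per assembly component, all libraries in 1 fit, the queen block and libraries left out. Other splits of the libraries were drawn, 100 per comparison for edgeR and 40 for DESeq2. DESeq2 after filterByExpr, most of the fits that leave out 1 library and the fits without old brains O-603 and O-796 were chosen after seeing the data. The planned run with descriptions from every deposited table coincides with the main one and was not run apart.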

Results

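The series asked how gene expression changes with age in long-lived ant queens. Brain and fat body, the insect organ of storage and metabolism, were taken from 8 old and 8 young field-collected queens of Temnothorax rugatulus. Total counts per library were 13861667 to 27434445 in old brains, 23826705 to 33461227 in young brains, 22798433 to 29614630 in old fat bodies and 20658985 to 31200003 in young fat bodies. The 100 most abundant contigs took 52.2% ± 3.9 (SD, n = 8) of the counts in old fat bodies and 42.4% ± 4.7 in young ones, against 19.7% ± 2 in old brains and 21.5% ± 1.4 in young brains.

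In the fat body, transcripts of a fatty acyl-CoA reductase, the enzyme henna and semaphorin-5B were higher in old queens, and those of Rab-32, the kinase mos and pellino were lower. The contig named putative fatty acyl-CoA reductase CG5065 stood at 11.7 ± 5.98 CPM (SD, n = 8) in old and 0.549 ± 0.31 CPM in young fat bodies, a log2 difference of 4.41 ± 0.45 (SE; edgeR adjusted p = 0.00042). Protein henna, the phenylalanine hydroxylase that makes tyrosine, rose from 17 ± 7.27 to 113 ± 64 CPM (log2 difference 2.73 ± 0.35, adjusted p = 0.0034). Rab-32, a small GTPase of vesicle traffic, stood at 45.3 ± 18.2 CPM in young and 7.72 ± 3.34 CPM in old fat bodies (log2 difference -2.55 ± 0.33, adjusted p = 0.0034). In each of these 3 cases all 8 old libraries lay on the same side of the young median.

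Of 27664 contigs tested in the fat body, 179 passed the threshold, 125 higher and 54 lower in old queens, and 111 of them had a protein name. Other contigs higher in old fat bodies were choline transporter-like protein 1 (log2 difference 2.2 ± 0.29, adjusted p = 0.0034), a major facilitator superfamily domain-containing protein 1-like transporter (1.41 ± 0.2, adjusted p = 0.0059), semaphorin-5B (2.44 ± 0.35, adjusted p = 0.0065) and laminin subunit beta-1, a basement membrane protein (1.68 ± 0.26, adjusted p = 0.01). Semaphorin-5B was the most abundant of them, at 1590 ± 498 CPM in old and 294 ± 127 CPM in young fat bodies. The largest subunit of RNA polymerase I, RPA1, which transcribes ribosomal RNA, rose from 218 ± 46.7 to 470 ± 109 CPM (log2 difference 1.11 ± 0.18, adjusted p = 0.012). Myb-like protein AA (2.76 ± 0.46, adjusted p = 0.018), shisa-5-like (0.87 ± 0.15, adjusted p = 0.018) and leukotriene A-4 hydrolase (1.23 ± 0.21, adjusted p = 0.02) rose as well. Lower in old fat bodies were the serine/threonine kinase mos (log2 difference -1.01 ± 0.16, adjusted p = 0.01) and pellino, an adaptor of Toll signalling (-0.84 ± 0.13, adjusted p = 0.01). N-alpha-acetyltransferase 50 (-0.84 ± 0.14, adjusted p = 0.015), a coiled-coil and C2 domain-containing protein 2A-like contig (-2.64 ± 0.43, adjusted p = 0.017) and protein lin-54 homolog (-0.79 ± 0.13, adjusted p = 0.018) also fell. Heat shock protein beta-1 (-1.66 ± 0.29), calcium uptake protein 3 of the mitochondrion (-1.31 ± 0.23), tetratricopeptide repeat protein 37 (-0.87 ± 0.15) and eukaryotic initiation factor 4A-III (-0.77 ± 0.14) fell with an adjusted p of 0.023 each. The contig with the smallest adjusted p, 2.7e-05, had an ant hit without a protein name and stood at 177 ± 25.9 CPM in old and 30 ± 10.4 CPM in young fat bodies.

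**Figure D1:**
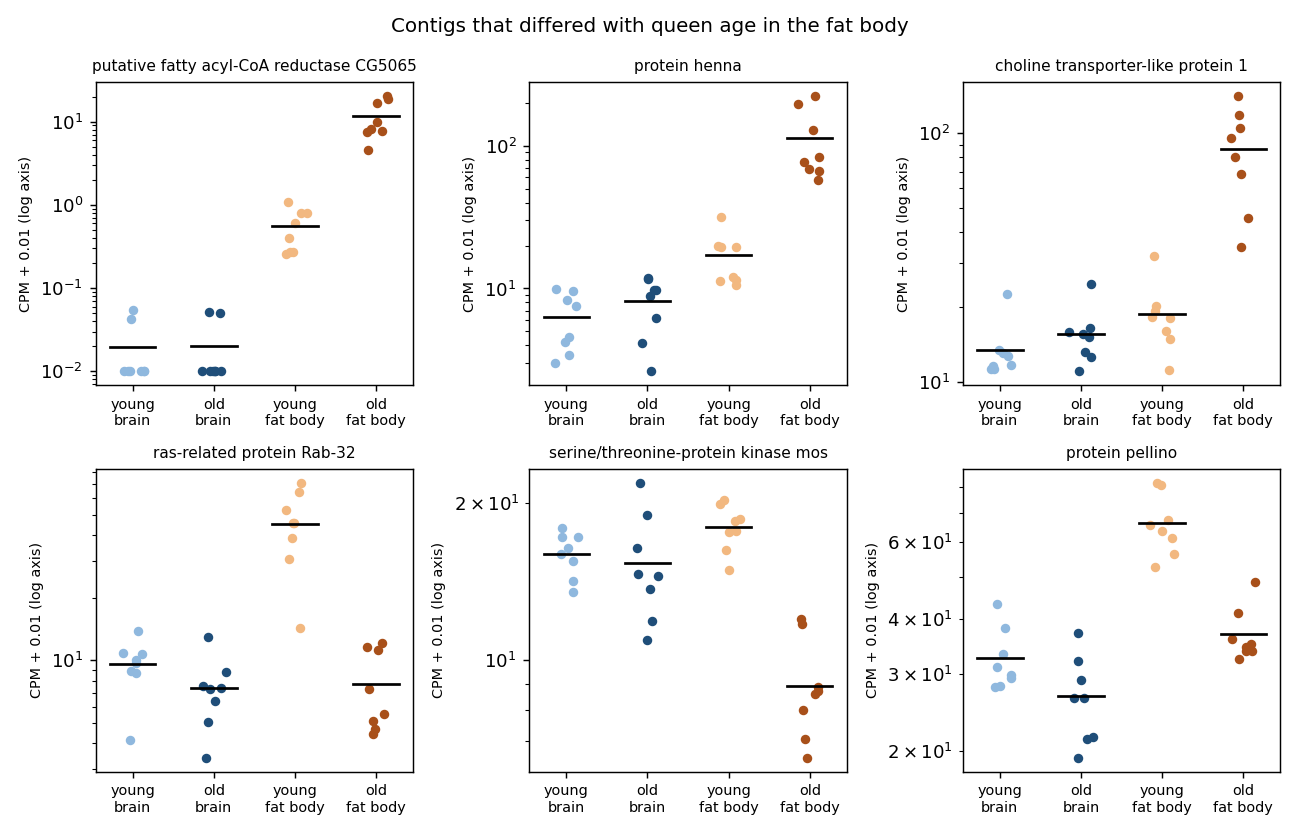
CPM per library on a log axis (0.01 added) for the 3 named contigs with the smallest adjusted p in each direction in the fat body, with 8 libraries per group and the group mean as a bar. Putative fatty acyl-CoA reductase CG5065 averaged 11.7 CPM in old and 0.549 CPM in young fat bodies, and Rab-32 averaged 7.72 and 45.3 CPM.

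The number of calls varied with the test: DESeq2 called 1234, limma-voom 502, edgeR with all 32 libraries in 1 fit 2135, edgeR without a count filter 38, and edgeR on counts summed per assembly component 824, with 408 higher and 416 lower. Leaving out 1 library at a time gave 40 calls (without old fat body O-796) to 311 (without old fat body O-426), and 12 of the 16 libraries moved the count by over 1.5 times.

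The members of the gene lists were chosen by the authors on age in these libraries, and all 877 contigs of their fat body table tested here had an unadjusted p under 0.05. The counts adjusted over the list alone were thus largely fixed by that choice and are not independent evidence of a change or of its direction. Of 21 tested ribosomal protein contigs, 20 had lower values in old queens and 3 fell over all contigs tested, 20 adjusted over the list alone. The authors' deposited table for the fat body lists 48 more ribosomal protein contigs, left out here by the count filter, all 48 higher in old queens and 42 with a best hit outside Hymenoptera. 60S ribosomal protein L10a stood at 253 ± 50.2 CPM in old and 452 ± 83 CPM in young fat bodies (log2 difference -0.83 ± 0.16, adjusted p = 0.027). 60S acidic ribosomal protein P1 (-0.73 ± 0.15, adjusted p = 0.042) and L11-like (-0.9 ± 0.19, adjusted p = 0.044) also fell. The list stood apart from the other described contigs in camera (adjusted p = 0.0076), and adjusted p = 0.47 with an estimated correlation. Of 15 proteasome, ubiquitin and autophagy contigs, 14 had lower values, 2 fell and 1 rose, or 14 lower and 1 higher adjusted over the list alone. The authors' table lists 6 more below the count filter, all 6 higher in old queens and 4 with a best hit outside Hymenoptera. Camera gave adjusted p = 0.048 for this list, adjusted p = 0.47 with an estimated correlation and adjusted p = 0.068 with 1 contig per description. Proteasome maturation protein, an assembly factor, fell (log2 difference -0.7 ± 0.15, adjusted p = 0.048), as did small ubiquitin-related modifier 3 (-0.54 ± 0.12, adjusted p = 0.049), while E3 ubiquitin-protein ligase CBL-B rose (1.21 ± 0.25, adjusted p = 0.041).

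Of 17 lipid metabolism contigs, 4 rose and 1 fell, or 9 higher and 7 lower adjusted over the list alone. The authors' table lists 10 more below the count filter, all 10 higher in old queens. Contigs named fatty acyl-CoA reductase 1-like (log2 difference 5.09 ± 0.95, adjusted p = 0.026), acyl-CoA Delta(11) desaturase-like (3.16 ± 0.66, adjusted p = 0.044) and fatty acid synthase (4.27 ± 0.92, adjusted p = 0.046) rose. They averaged 18.6, 2.6 and 2.56 CPM in old and 0.55, 0.285 and 0.131 CPM in young fat bodies, so their young levels were low. For this desaturase contig 2 old libraries lay below the young median. Another contig of the same desaturase description fell from 159 to 30.9 CPM (-2.36 ± 0.51, adjusted p = 0.046). A fatty acid synthase-like contig had a log2 difference of -2.99 ± 0.93 (adjusted p = 0.14). The last 2 were singled out after their values were seen. Of 15 detoxification contigs 2 rose and 0 fell, or 3 higher and 9 lower adjusted over the list alone. Below the filter 3 more are listed as higher and 2 as lower. The ATP-binding cassette sub-family G member 1-like transporter (1.66 ± 0.29, adjusted p = 0.023) and cytochrome P450 6k1-like (1.41 ± 0.31) rose, and cytochrome P450 4c3-like had a log2 difference of -3.25 ± 0.74 (adjusted p = 0.056). Of 12 chromatin and histone contigs 1 rose and 2 fell, or 2 higher and 10 lower adjusted over the list alone. Below the filter 2 more are listed, both higher. Histone H3.3 fell from 45.9 ± 8.48 to 29.1 ± 2.63 CPM (adjusted p = 0.035), as did the SDS3 component of the sin3 deacetylase complex (-0.97 ± 0.19, adjusted p = 0.027), while lysine-specific histone demethylase 1 homolog 3-like rose (2 ± 0.43, adjusted p = 0.047). Of 9 heat shock and chaperone contigs 1 rose and 1 fell, or 4 higher and 4 lower adjusted over the list alone, the riser being heat shock protein 67B2-like (1.42 ± 0.31, adjusted p = 0.049). Below the filter 7 more chaperone contigs are listed, all 7 higher in old queens and 5 with a best hit outside Hymenoptera.

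Of 6 antioxidant contigs 1 rose, peptide methionine sulfoxide reductase, which repairs oxidised methionine (3.28 ± 0.65, adjusted p = 0.033), and 4 were higher and 2 lower adjusted over the list alone. Below the filter 8 more are listed, all 8 higher in old queens and 6 with a best hit outside Hymenoptera. Phospholipid hydroperoxide glutathione peroxidase had a log2 difference of -0.9 ± 0.21 (adjusted p = 0.055). Of 5 immunity contigs 1 rose, the pathogen-sensing beta-1,3-glucan-binding protein-like contig, from 686 ± 177 to 1950 ± 863 CPM (1.51 ± 0.28, adjusted p = 0.026), or 4 higher and 1 lower adjusted over the list alone. Below the filter 1 more is listed as higher and 1 as lower. The iron-binding protein transferrin stood at 3150 ± 1610 CPM in old and 444 ± 624 CPM in young fat bodies (adjusted p = 0.081). Krueppel homolog 1-like, a transcription factor of the juvenile hormone response, fell (-0.72 ± 0.13, adjusted p = 0.025), the only tested member of its list. Of 4 oxidative phosphorylation contigs 1 fell, cytochrome c oxidase subunit 4 isoform 1 (-0.59 ± 0.13, adjusted p = 0.047). Of 5 neuronal signalling contigs 1 fell, neuroligin-1-like (-0.65 ± 0.14). Adjusted over the list alone, 1 was higher and 3 were lower of the oxidative phosphorylation contigs, and 1 was higher and 4 were lower of the neuronal ones. The authors' table lists 11 more oxidative phosphorylation contigs below the filter, all 11 higher in old queens and 10 with a best hit outside Hymenoptera. It also lists 3 more neuronal ones, all 3 higher. Camera gave an adjusted p of at least 0.17 for these lists and for the lipid, detoxification, chromatin and chaperone lists. None of the 2 DNA repair, 2 chemosensory, 1 transposable element, 1 cuticle and 1 apoptosis contigs passed edgeR's threshold over all contigs. All of them were under 0.05 adjusted over the list alone, which for a list of 1 is its unadjusted p and which follows from how the contigs were chosen. Below the filter 1 chemosensory and 1 cuticle contig are listed as higher and 1 DNA repair contig as lower. No described contig matched the insulin and TOR or the royal jelly and yellow list.

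Among 2 haemocyte contigs, protein croquemort-like, a scavenger receptor of blood cells, rose (1.08 ± 0.22, adjusted p = 0.04), and of 2 venom and gland contigs venom dipeptidyl peptidase 4 rose (1.14 ± 0.22, adjusted p = 0.029). Of 6 contigs matching the gut and Malpighian tubule list 0 passed over all contigs and 5 were higher and 1 lower adjusted over the list alone. The lower one was antichymotrypsin-2-like, caught by the word trypsin within its name and not a trypsin. The higher ones include a contig named as a lysosomal alpha-glucosidase. Also among the higher ones, maltase 2-like stood at 407 ± 299 CPM in old and 60.7 ± 40.9 CPM in young fat bodies. Of 6 fat body markers 2 rose and 1 fell. Below the filter 4 more fat body markers and 2 gut contigs are listed, all higher in old queens, and 1 photoreceptor contig, lower. The single germline, muscle and glia contigs had lower values in old queens and did not pass over all contigs, and the 1 contig caught by the virus and parasite list, a retrovirus receptor-like protein and not a virus, rose (1.62 ± 0.28, adjusted p = 0.023). No neuron or photoreceptor marker passed the count filter in the fat body, where the neuronal gene complexin stood at 1.37 ± 1.48 CPM in old and 0.27 ± 0.133 CPM in young queens, with all 8 old libraries above the young median. The authors' table lists complexin as higher in old fat bodies (log2 difference 2.06, authors' adjusted p = 0.015). In the edgeR test of the difference between tissues it had a higher fat body difference (2.77 ± 0.61, adjusted p = 0.047, and 0.24 with the queen as a block).

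**Figure D2:**
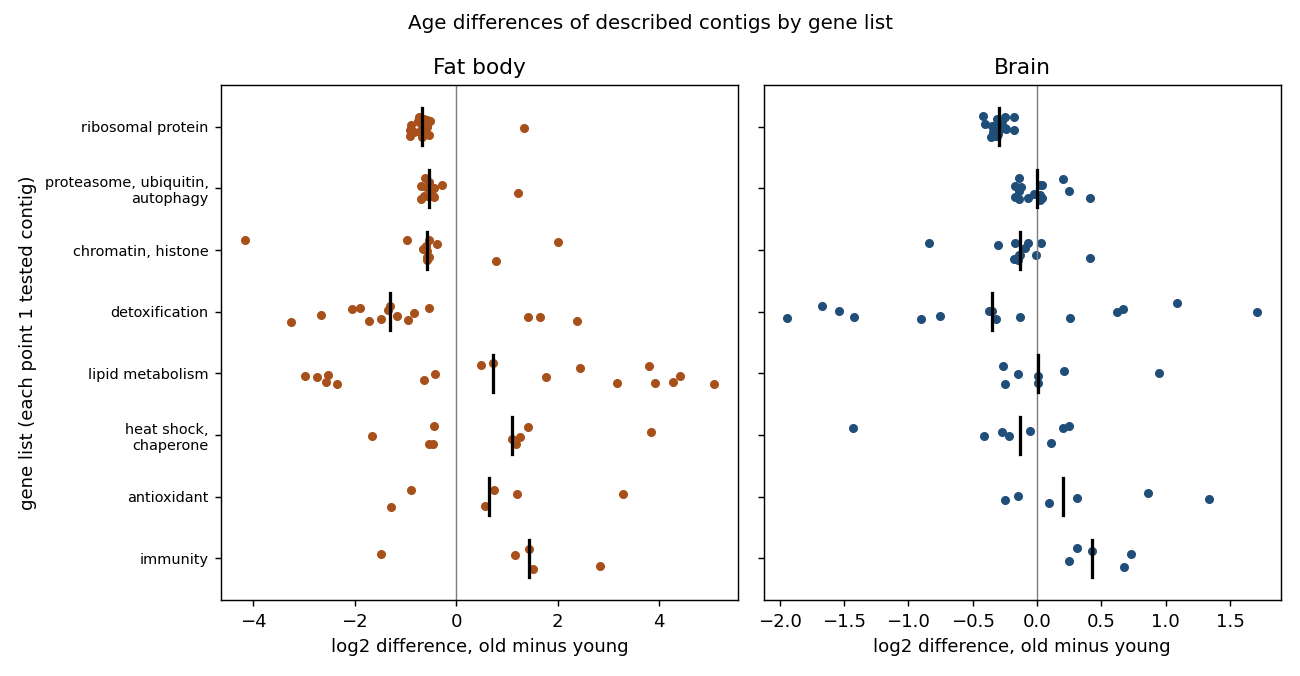
Log2 difference between old and young queens for each tested contig of 8 gene lists, in fat body (left) and brain (right), with the list median as a bar. Ribosomal protein contigs lie below 0 for 20 of 21 in the fat body and 20 of 20 in the brain, for contigs that passed the count filter. The members were selected by the authors on age in these libraries.

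In the brain, no contig of 40572 tested passed edgeR's threshold between old and young queens, so the values below are differences that did not pass. Cytochrome P450 9e2-like, of a family of detoxifying enzymes, stood at 39.9 ± 14.4 CPM (SD, n = 8) in old and 153 ± 93.4 CPM in young brains (log2 difference -1.94 ± 0.35, edgeR adjusted p = 0.3), with all 8 old brains below the young median. DnaJ homolog subfamily B member 6, a co-chaperone, stood at 7.41 ± 2.74 and 19.9 ± 9.06 CPM (-1.43 ± 0.3, adjusted p = 0.37). Thioredoxin domain-containing protein 11 stood at 19.2 ± 4.15 CPM in old and 7.57 ± 4.57 CPM in young brains (adjusted p = 0.53), and the neuronal acetylcholine receptor subunit alpha-7-like at 9.08 ± 2.77 and 5.03 ± 1.09 CPM (adjusted p = 0.55). EdgeR called 0 contigs, with 1882 (4.64%) at an unadjusted p under 0.05. DESeq2 called 623, of which 489 were higher in old brains, and 139 higher and 50 lower after filterByExpr, and limma-voom called 0.

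The 20 tested ribosomal protein contigs all had lower values in old brains, with a median log2 difference of -0.29, and 0 passed, over all contigs or adjusted over the list alone. The authors' deposited table for the brain lists 21 more ribosomal protein contigs, left out here by the count filter, all 21 higher in old queens and 17 with a best hit outside Hymenoptera. Camera placed the list below the other described contigs (adjusted p = 0.00098), and adjusted p = 0.64 with an estimated correlation. All 5 immunity contigs had higher values in old brains, with a median of 0.43 and 0 calls (camera adjusted p = 0.17). Of 15 detoxification contigs 1 was higher and 5 were lower adjusted over the list alone, and 0 passed over all contigs. Adjusted over the list alone, 1 of 6 antioxidant, 1 of 7 lipid and 1 of 8 neuronal contigs were higher in old brains, and 2 of 8 chaperone, 1 of 3 oxidative phosphorylation and 1 of 2 chemosensory contigs were lower. Below the count filter, the authors' table for the brain lists 3 chaperone, 2 antioxidant, 1 detoxification, 1 neuronal, 1 oxidative phosphorylation, 1 proteasome and ubiquitin and 1 muscle contig, all higher in old queens. It also lists 1 lipid contig as higher, 1 as lower and 1 chemosensory contig as lower. Of 16 proteasome and ubiquitin, 12 chromatin, 2 DNA repair, 1 juvenile hormone, 1 cuticle and 1 apoptosis contigs 0 passed either way, and no transposable element contig was tested. Camera gave an adjusted p of at least 0.17 for every list with at least 3 tested contigs other than the ribosomal one. These descriptions too were chosen by the authors on age in these queens, 117 from their brain table and 963 from their fat body table. Most were thus chosen on the fat bodies of the same queens, whose deviations from the group means correlate with those of their brains. All 56 contigs of the brain table tested here had an unadjusted p under 0.05. Neither the direction of a list in the brain nor its counts adjusted over the list alone are thus independent evidence. The 1 neuron, 1 photoreceptor, 1 glia, 1 muscle and 1 germline marker and the haemocyte, venom, gut and fat body markers gave 0 edgeR calls over all contigs, as did the retrovirus receptor-like contig. The muscle contig, tropomyosin-1, had a log2 difference of -0.83 ± 0.37 (adjusted p = 1) and the photoreceptor contig, an arrestin, one of -1.09 ± 0.38 (adjusted p = 0.9). As the only tested members of their lists they were under 0.05 adjusted over the list alone, which is their unadjusted p (0.041 and 0.01).

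Among the described contigs, superoxide dismutase and catalase, which remove superoxide and hydrogen peroxide, were represented only by contigs too low for the main test. Contigs of these enzymes that the authors did not list with age carry no description, so the values below do not give the enzymes' full levels. The contigs shown were chosen on age in these libraries, so their direction is not independent evidence. Whether they are the ant's own was not tested. The 2 superoxide dismutase contigs averaged 0.991 and 0.188 CPM in old brains and 0.00445 and 0 CPM in young brains. In the fat body they averaged 0.597 and 0.202 CPM in old and 0.0708 and 0.0658 CPM in young queens. The catalase contig with the higher level averaged 1.45 ± 2.51 CPM in old and 0.0284 ± 0.0426 CPM in young brains, and 0.919 ± 0.8 and 0.0593 ± 0.0848 CPM in fat bodies. Its best database hit was a mite, and those of the superoxide dismutase contigs were a sawfly and a fruit fly. The other catalase contig, with a parasitoid wasp as best hit, averaged 0.1 ± 0.103 CPM in old fat bodies and had no count in young ones. No described contig was named vitellogenin.

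Among the contigs higher in old queens, the authors' deposited table lists 52 for the brain and 177 for the fat body whose best hit lay outside Hymenoptera, the order of ants, bees and wasps. Of them 51 and 174 had too few counts for the tests made here. Of the 177, old fat bodies had a count for 135 ± 41 (SD, n = 8) and young fat bodies for 19.2 ± 10.8, in the libraries on which the contigs were chosen. Of all contigs, old fat bodies had a count for 73635 ± 8330 and young ones for 63912 ± 7000. With each fat body library randomly reduced to 20658985 counts, 130 of the 177 were detected in old and 18.1 in young ones on average. In the brains of the same queens, 92.5 ± 49.4 were detected in old and 13.8 ± 6.84 in young queens (2-sided exact permutation p = 0.0019). This p does not allow for the choice of the contigs on the fat bodies of the same queens, whose 2 tissues vary together. Old brains O-426 and O-829, with 15 and 21, lay within the 5 to 24 of the young brains, and the other 6 old brains had 85 to 150. Their summed level, 203 ± 38.7 CPM in old and 196 ± 50.6 CPM in young brains (2-sided exact permutation p = 0.75), was carried by few contigs, as in young brain Y-651, where 8 detected contigs held 280 CPM, and does not describe the others. Among the contigs higher in young fat bodies, the authors' deposited table lists 37 with a best hit outside Hymenoptera. Of these 31.8 ± 6.23 were detected in young and 10.1 ± 2.1 in old fat bodies, the libraries on which they were chosen. In brains 19.9 ± 3.98 were detected in young and 19.2 ± 4.59 in old queens (2-sided exact permutation p = 0.82). Of the 52 listed as higher in old brains, 40 ± 10 were detected in old and 28 ± 7.87 in young fat bodies (2-sided exact permutation p = 0.023).

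**Figure D3:**
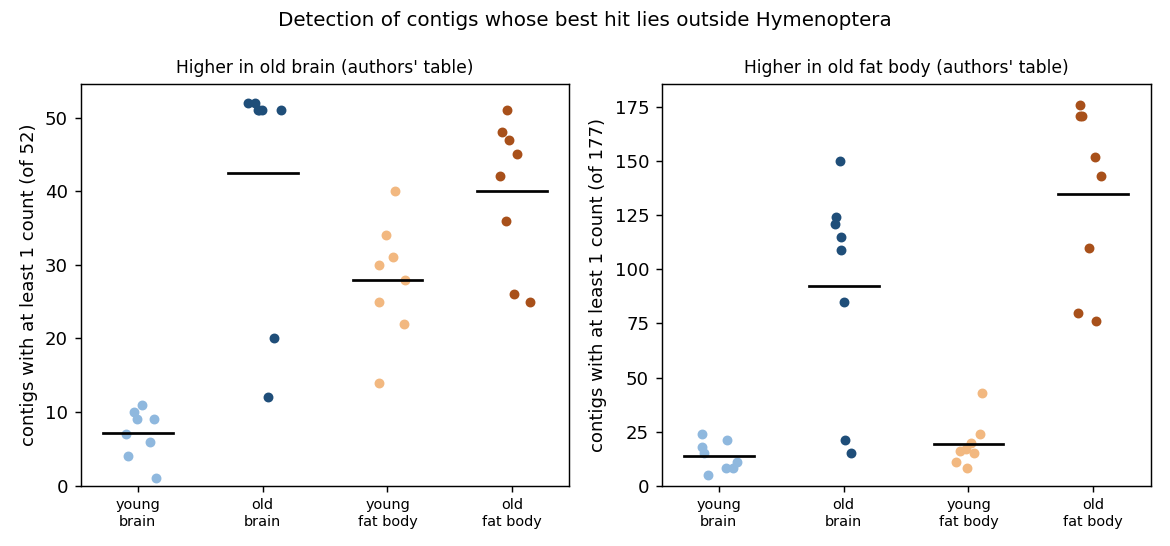
Number of contigs with at least 1 count in each library, for the 52 and 177 contigs with a best hit outside Hymenoptera that the authors' deposited table lists as higher in old brains (left) and old fat bodies (right), with 8 libraries per group as points and the group mean as a bar. In old fat bodies 76 to 176 of the 177 were detected, and in young fat bodies 8 to 43.

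Comparing the authors' deposited table for the brain with these fits, 56 of its 169 contigs were tested here, all 56 had the same direction and 0 passed. Of the 1597 contigs in the authors' deposited table for the fat body, 877 were tested here, all with the same direction, and 169 passed. The authors' deposited table for the brain lists 133 contigs higher in old and 36 higher in young queens, and the one for the fat body 1062 and 535.

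The age difference differed between tissues for 109 of 48253 contigs, 89 with a higher and 20 with a lower fat body difference. Semaphorin-5B differed by 2.2 ± 0.37 on the log2 scale (edgeR adjusted p = 0.0076), choline transporter-like protein 1 by 2.03 ± 0.34 (adjusted p = 0.0076) and the major facilitator 1-like transporter by 1.43 ± 0.21 (adjusted p = 0.003). Purine nucleoside phosphorylase, a nucleoside salvage enzyme, averaged 173 CPM in old and 11.4 CPM in young fat bodies against 34.2 and 52 CPM in old and young brains (4.53 ± 0.82, adjusted p = 0.013). A glucose transporter of the solute carrier 2 family averaged 382 and 33.9 CPM in old and young fat bodies and 155 and 149 CPM in brains (3.44 ± 0.64, adjusted p = 0.016). Coatomer subunit beta (3.3 ± 0.57, adjusted p = 0.0085), myb-like protein AA (2.74 ± 0.51, adjusted p = 0.016) and a purine nucleoside phosphorylase-like contig (4.96 ± 0.93, adjusted p = 0.016) had higher fat body differences as well. Rab-32 (-2.13 ± 0.42, adjusted p = 0.021), the kinase mos (-0.92 ± 0.2, adjusted p = 0.041) and peptidyl-tRNA hydrolase PTRHD1 (-1.36 ± 0.3, adjusted p = 0.041) had lower ones. Among the members of the gene and marker lists, the ATP-binding cassette G member 1-like transporter (2.05 ± 0.42, adjusted p = 0.025), the retrovirus receptor-like contig (1.56 ± 0.3, adjusted p = 0.018) and the neuron marker complexin (2.77 ± 0.61, adjusted p = 0.047) passed, all with a higher fat body difference. With the queen as a block the count was 2, Rab-32 (adjusted p = 0.037) and an unnamed contig (adjusted p = 0.00015), and the other contigs named here had adjusted p values of 0.05 to 0.34. The count was 60 without young brain Y-134 and 55 without old brains O-603 and O-796, which stood apart from the other brains.

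Across 23824 contigs tested in both tissues, the age differences correlated at r = 0.275 (Spearman rho 0.244); contigs are not independent replicates. Reassigning whole queens to the ages gave a correlation at least as high in 31 of 40 assignments, the real one included, with a median of 0.343 for the others.

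Between the tissues of young queens, complexin, a regulator of synaptic vesicle release whose best hit was a stink bug, averaged 148 ± 38.7 CPM (SD, n = 8) in the brain and 0.41 ± 0.205 CPM in the fat body (log2 difference, fat body minus brain, -8.49 ± 0.38, edgeR adjusted p = 7.3e-11). Cationic amino acid transporter 2 differed by -8.33 ± 0.46 and GRAM domain-containing protein 3-like by -6.15 ± 0.34. Leishmanolysin-like peptidase (-3.19 ± 0.14), leukotriene A-4 hydrolase (-3.55 ± 0.2), sestrin-3 (-4.66 ± 0.29), G-protein coupled receptor 158 (-4.61 ± 0.32) and lysine-specific demethylase 7A-like (-2.7 ± 0.2) were also higher in the brain. The beta-1,3-glucan-binding protein-like contig averaged 1040 ± 277 CPM in the fat body and 46.6 ± 11.1 CPM in the brain (4.48 ± 0.23, adjusted p = 2.8e-10). Venom dipeptidyl peptidase 4 (4.15 ± 0.21), the clock-related aryl hydrocarbon receptor nuclear translocator-like protein 1 (3.91 ± 0.21), centromere-associated protein E (3.33 ± 0.18), proteasome subunits beta type-5 (2.36 ± 0.13) and type-6 (2.64 ± 0.15), unc-13 homolog D (1.62 ± 0.09) and spidroin-2-like (1.72 ± 0.1) were higher in the fat body. Of 35113 contigs, 8073 were higher in the fat body and 11953 higher in the brain. The named contigs come only from those described for age.

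In old queens, semaphorin-5B averaged 2370 ± 776 CPM in the fat body and 32.1 ± 6.9 CPM in the brain (6.21 ± 0.25, edgeR adjusted p = 8.4e-11). Carbohydrate sulfotransferase 11-like (6.34 ± 0.34), venom dipeptidyl peptidase 4 (5.47 ± 0.31), the ATP-binding cassette G member 1-like transporter (4.91 ± 0.28), laminin subunit alpha (4.69 ± 0.27), centromere-associated protein E (4.71 ± 0.23), a mitochondrial nudix hydrolase (4.87 ± 0.27) and enoyl-CoA hydratase of fatty acid oxidation (3.95 ± 0.22) were also higher in the fat body. Complexin averaged 95.2 ± 31.8 CPM in old brains and 2.02 ± 2.15 CPM in old fat bodies (-5.56 ± 0.61, adjusted p = 1.1e-06). Quiver (-4.7 ± 0.48), cationic amino acid transporter 2 (-5.25 ± 0.6), G-protein coupled receptor 158 (-3.95 ± 0.25), sestrin-3 (-3.37 ± 0.29), a band 3 anion transport protein (-2.87 ± 0.28), leukotriene A-4 hydrolase (-2.24 ± 0.13) and a spliceosomal 27 kDa protein (-1.95 ± 0.15) were higher in the brain. Of 34574 contigs, 9035 were higher in the fat body and 10265 in the brain. All tested ribosomal protein contigs were higher in the fat body, 20 in young and 21 in old queens, as were the 5 immunity contigs in both ages. With the queen as a block 20 of the 21 ribosomal protein contigs passed in old queens and 4 of the 5 immunity contigs in young queens, where transferrin had a log2 difference of 0.66 (adjusted p = 0.25). Of the lipid metabolism contigs 8 of 10 in young and 12 of 14 in old queens were higher in the fat body. Of 12 chromatin contigs 4 were higher in the fat body and 3 in the brain of young queens (3 and 2 with the queen as a block). In old queens the counts were 2 and 6. The difference of these counts between ages was not tested. Most of the chromatin contigs were described for being lower in old fat bodies, so it is not independent evidence. Median-of-ratios scaling moved the median log2 difference of all contigs in old queens from -0.05 to -0.234. DESeq2 called 39200 contigs in young and 35942 in old queens, and edgeR without a count filter 51185 and 38356.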

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

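The test of sequencing depth for the contigs with hits outside Hymenoptera was chosen after the result was seen, and the other tests in this part were set before their results.

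Among 60 groups of 8 libraries or values, 9 held 1 library far from the others (the gap to the nearest library over the range exceeded Dixon's critical ratio). Chance gives about 1 in 20 for normally distributed values. The values here were unlogged CPM and counts, and each of the 9 libraries was the highest of its group. That rate may therefore not hold, and the 9 are not shown to exceed chance. Old fat body O-482 had 92049 contigs detected, against 64464 to 76450 in the other old fat bodies. Protein henna stood at 31.7 CPM in young fat body Y-453 (10.6 to 20 in the others), and choline transporter-like protein 1 at 32.1 CPM in Y-651 (11.1 to 20.2). The major facilitator 1-like transporter stood at 180 CPM in old fat body O-189 (61 to 108 in the others). The coiled-coil and C2 domain-containing protein 2A-like contig stood at 1.73 CPM in old fat body O-426 (0.245 to 0.833 in the others) and at 8.01 CPM in young fat body Y-333 (2.76 to 4.57). Heat shock protein beta-1 stood at 31.6 CPM in old fat body O-269 (10.5 to 16.5 in the others) and at 98.9 CPM in young fat body Y-503 (26.9 to 58.5). Young fat body Y-651 had a count for 43 of the 177 contigs with a hit outside Hymenoptera, against 8 to 24 in the other young fat bodies.

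The test of the difference between tissues itself called 109 contigs. The named ones had differences of log2 age differences of 1.43 for the major facilitator 1-like transporter, 2.03 for choline transporter-like protein 1, 2.2 for semaphorin-5B, 3.3 for coatomer subunit beta, 4.53 for purine nucleoside phosphorylase, 3.44 for the solute carrier 2 glucose transporter, 2.74 for myb-like protein AA and 4.96 for purine nucleoside phosphorylase-like. They were -2.13 for Rab-32, -1.36 for PTRHD1 and -0.92 for the kinase mos. In 1 of 100 reassignments of whole queens, the real one included, as many contigs were called, and the highest other count was 12. A chance assignment of queens to ages can thus be excluded for the count. Such reassignments remove the age difference from both tissues at once, so they cannot decide whether it differs between tissues. With the queen as a block 2 contigs passed.

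Contigs with a best hit outside Hymenoptera that the authors' deposited table lists as higher in old queens, 51 for the brain and 174 for the fat body, were left out of the tests by the count filter, while 37 with such a hit were listed as higher in young fat bodies. The 177 listed for the fat body varied together across the 8 old fat bodies, with a mean pairwise Spearman rho of 0.36. In 1000 draws of ant-hit contigs matched on abundance, with a median of 68 distinct ones per draw, the median was 0 and the 95th percentile 0.012. Reads from another organism in old queens would give such shared variation and are a hypothesis for these 177. It does not cover the 37 that go the other way, nor old brains O-426 and O-829 (15 and 21 detected, against 5 to 24 in young brains). Of the 52 listed for the brain, 40 ± 10 were detected in old and 28 ± 7.87 in young fat bodies (SD, n = 8), so such contigs also occur in young queens. The 177 also hold complexin, which stood at 151 ± 47.8 CPM in old and 202 ± 52.1 CPM in young brains, so not all are rare in the ant's own tissue. Greater depth is argued against in the brains. Old brains held fewer counts (13861667 to 27434445 against 23826705 to 33461227 in young brains). Yet 88.9 ± 48.9 of the 173 contigs listed only for the fat body were detected in old and 13 ± 6.44 in young brains (SD, n = 8, 2-sided exact permutation p = 0.0023). That p does not allow for the choice of these contigs on the fat bodies of the same queens. Old brains also had a count for more contigs in all, 96537 ± 5320 against 91754 ± 4310 in young brains. Age, colony and collection of the queens stay open as untested.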

How the results depend on the processing

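The fits leaving out 1 library (other than young brain Y-134), the fits without old brains O-603 and O-796, and DESeq2 after filterByExpr were chosen after seeing the data. For age in the brain, edgeR called 0 contigs (1882 at an unadjusted p under 0.05), 4 with all 32 libraries in 1 fit, DESeq2 623, and 139 higher and 50 lower in old queens after filterByExpr. Leaving out 1 library gave 0 to 1, the 1 without O-469. For age in the fat body the 179 calls became 38 with no filter, 502 with limma-voom, 824 per component, 2135 with all 32 libraries, 1234 with DESeq2, and 813 higher and 657 lower with DESeq2 after filterByExpr. Leaving out 1 library gave 40 to 311: 94 without O-189, 91 without O-269, 311 without O-426, 87 without O-469, 54 without O-603, 40 without O-796, 98 without O-829, 100 without Y-102, 64 without Y-134, 106 without Y-361, 80 without Y-503 and 54 without Y-594. Of 460 values of the 20 named fat body contigs 440 kept their call, 20 lost it and 0 reversed, and 9 contigs kept it in every setting. Between tissues, the calls became 51185 with no filter and 39200 with DESeq2 in young queens, and 38356 and 35942 in old queens, and all 128 values of the named contigs in each age kept their call. The 109 contigs differing between tissues became 38 with no filter, 213 per component, 982 with DESeq2, 55 without O-603 and O-796, 60 without Y-134, and 2 with the queen as a replicate block, which moved no other count by over 1.5 times. Named contigs there kept their call in 67 of 88 values. The correlation of age differences was 0.358 on log2 CPM. The 3 gene list calls for age became 0 with an estimated correlation. Fits with no filter test more contigs. Fits leaving out 1 library hold fewer libraries, yet their fat body calls went both down and up, from 40 to 311. Whether either accounts for the moved counts was not tested. A test of the fits per component, under the other observations, could not decide, and for the other settings the cause was not tested. Depth limits the tests of low contigs, which the filter leaves out.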

Other observations

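Among the tests in this part, DESeq2 after filterByExpr was chosen only after the results were seen.

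In the fat body, the real ages called 179 contigs, reached by 1 of 100 splits of the libraries with the real one included, and the highest other split called 1, so chance can be excluded for the count. In the brain the real count was 0, which all 100 splits reach by construction (highest other 1), so the splits say nothing about chance there. DESeq2 after filterByExpr called 139 contigs higher and 50 lower in old brains, reached by 1 of 40 splits, the real one included. That is the smallest share 40 splits can give. The highest other split called 43, so chance can be excluded for that count as a whole, though not for single contigs. Its 1470 fat body calls were reached by 1 of 40 splits, the highest other calling 501, so chance can be excluded for that count too, with the same limit. On simulated data DESeq2 gave 83 false calls among 181 for the brain and 71 among 139 for the fat body. Those counts were drawn independently for each contig, with dispersions estimated by edgeR. The 83 exceed the 43 of the highest other brain split, and the 71 lie below the 501 of the fat body. The simulated false calls may therefore not give the rate in these data. EdgeR and limma-voom called 0 contigs with age in the real brains. Between tissues, 1 of 100 swaps within queens reached the 20026 calls of young queens (highest other 7542) and 1 of 100 the 19300 of old queens (highest other 8359), so chance can be excluded for both. The correlation of age differences between tissues, 0.275, was reached by 31 of 40 reassignments of whole queens (highest other 0.394), so chance cannot be excluded for it.

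Summing counts per assembly component raised the fat body calls to 824, and 160 of the 170 components holding a called contig were among them. A candidate explanation is that reads are divided between contigs of 1 component. The share of tests with p under 0.001 rose 4.11 times in components of several tested contigs and 1.41 times in those of 1, a ratio of gains of 2.92. The first components held 3.2 tested contigs each, and a component that takes the p of its 1 changed contig raises this share by up to as much with no division of reads. The test is therefore void, its bound of 1.5 set beforehand was too low, and divided reads and an effect of age itself both stay open.

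Ribosomal protein, proteasome and chromatin contigs, 48 in all, had a median log2 difference of -0.6 (SD 0.79 over contigs) in old fat bodies, where the 100 most abundant contigs took a larger share of the counts. Leaving out those 100 contigs hardly changed the scaled fit, with a median of -0.61 and 172 calls, so it could not show whether their share matters, and this explanation stays open. A contig length bias is argued against as the whole cause, since with the length trend removed the median was -0.67. A difference of age in these genes may remain as a hypothesis, untested here on contigs that the authors chose on age in these libraries. The authors' deposited table for the fat body also lists 55 contigs of these lists below the count filter, all higher in old queens. Of these 55, 47 had a best hit outside Hymenoptera and 1 had an ant hit, and whether they are the ant's own was not tested.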
